A study of Drosophila melanogaster with 4 samples.

How the data were processed

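Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on nuclei of wild-type Oregon-R Drosophila melanogaster larvae of the last larval instar, with an antibody against dimethylated lysine 9 of histone H3 (H3K9me2). H3K9me2 is a histone modification of silent, compact chromatin. The labels describe 2 ChIP libraries and 2 input libraries, where input is sheared chromatin taken without immunoprecipitation. Each input library served as the reference for the ChIP library with the same replicate number, per the labels. Larvae were raised from population cages, tissue was homogenised and fixed with formaldehyde, and nuclei were lysed with SDS and sonicated, per the labels' protocols. Nothing in the labels says whether the replicates came from separate larval collections, so the spread between them may be technical.

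Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The coordinates are those of FlyBase release 5, per the file headers. The region caller, its thresholds and any read filter are not given in the sources used here. The 3 deposited files are lists of enriched regions: 1 list per ChIP library and 1 combined list made from the replicate set. How the authors combined the libraries is not given in the sources used here. Each region carries a deposited score, which is the authors' own enrichment value for that region. The scale and log base of the score are not stated, so the report uses scores only to rank or describe regions. The closing section also compares differences between scores, in score units, which assumes that the score is additive. No read counts accompany the regions, so sequencing depth is unknown and no interval for counting error was given. The input libraries have no region list of their own and entered only through the authors' calling.

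The lists differ in how they were made. The shortest region was 1301 bp in both replicate lists and 1001 bp in the combined list, and all starts were even in the combined list (100%) against 50.6% and 50.2% in the lists of replicates 1 and 2. A few regions ran past the end of a sequence as stated in the headers, namely 3 in replicate 1, 4 in replicate 2 and 5 in the combined list, by at most 954 bp, and were trimmed to that end. Regions named as depleted, 1 in replicate 2 and 2 in the combined list, were set aside. Regions within a list did not overlap. No list held a region on the unplaced sequence collection Uextra.

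Sequence lengths came from the file headers. Sequences were put into 4 classes: the 5 large arms (2L, 2R, 3L, 3R, X), chromosome 4, the 6 assembled heterochromatic sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet) and the unplaced sequence U. For each list the number of regions, the covered length and the covered share of each sequence were computed, and replicate values are given as mean ± SD with n = 2. With 2 replicates a two-sided permutation test over libraries cannot give a p below 0.5, so none was run. Tests were made over sequences, windows or placements, which are not independent biological replicates. Coverage of the 6 heterochromatic sequences was compared with that of the 5 large arms by an exact permutation test over 462 splits. Agreement between replicates was measured as the Jaccard index (bases covered in both lists over bases covered in either) and compared with 10000 circular shifts of the replicate 2 list within each sequence. On simulated lists of 300 regions of 2000 bp on 3R, this shift test called 3.5% of 200 unrelated pairs at a threshold of 0.05, and 100% of 50 pairs with 60 planted shared regions. The simulated regions had equal length and were placed uniformly. The check therefore does not cover long domains or densely covered sequences, where lists that agree only in broad domains could also be called.

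The proximal domain of an arm was the run of consecutive 100 kb windows, counted from its centromere-proximal end, of which at least 50% was covered. That end lies at high coordinates on 2L, 3L and X and at low coordinates on 2R and 3R. Region density outside the domain was compared between X and the 4 autosomal arms in windows of 1 Mb, with 100000 permutations of the window labels and a block bootstrap of 2000 draws for the 95% interval of the ratio. Regions named in the text are, by rule, the 3 longest of the combined list in each class, the 5 longest on the large arms outside the proximal domain that both replicates covered by at least 50%, and the 5 with the highest score. These rules, the tests of agreement and the proximal domain were set before the data were examined. The test over sequences, the comparison of X with autosomes and the uncovered stretches were chosen afterwards.

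Alternatives were minimum region lengths of 1000 bp and 2000 bp, merging of regions within 1000 bp, the 50% of each list with the highest scores, overlap of at least 50%, windows of 50 kb, a threshold of 25% of a window, and each replicate list alone. For X, windows of 5 Mb and the sequence more than 3 Mb from the proximal end of each arm were added. Gene-based comparisons (lists of pericentric, chromosome 4, Y-linked, Polycomb target, housekeeping and larval secretion genes, genes beside piRNA clusters, and the exon, intron and UTR content of regions) had been planned but were not made, because the gene table used here belongs to release 6 and its coordinates do not apply to release 5. No gene was named from coordinates for that reason. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.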

Results

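The data set profiled H3K9me2 in nuclei of wild-type Oregon-R larvae by ChIP-seq with a single antibody. It held 2 ChIP replicates, each called against its own input library, and a combined list. The question addressed is where along the fly genome this heterochromatin mark was enriched, and how well the replicates located it. Replicate 1 had 3667 enriched regions covering 25.9 Mb and replicate 2 had 4728 regions covering 24.4 Mb. The means were 4198 ± 750.2 regions and 25.1 ± 1.07 Mb (SD, n = 2), or 18.0% ± 0.765 (SD, n = 2) of the 139.7 Mb of sequence that carried regions. Replicate 2 thus had more but shorter regions, with a median length of 2499 bp against 3050 bp. The combined list had 5614 enriched regions over 33.0 Mb. The depth of the libraries is unknown from these lists.

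H3K9me2 enrichment covered most of the assembled heterochromatin and of chromosome 4, and little of the large arms. The 6 heterochromatic sequences, which are scaffolds placed in the repeat-rich chromatin around the centromeres and on the Y, were covered over 77.4% ± 3.54 of their 9.28 Mb (SD, n = 2). Chromosome 4, a small chromosome known for its heterochromatic character, was covered over 81.3% ± 2.41 of its 1.35 Mb (SD, n = 2). The unplaced sequence U was covered over 65.0% ± 12.3 of its 10.0 Mb (SD, n = 2), and the 5 large arms over 8.65% ± 0.446 of their 119.0 Mb (SD, n = 2). The heterochromatic sequences, chromosome 4 and U together make up a small part of the assembly but held the larger part of the enriched bases, since the large arms held 41.1% ± 3.87 of all covered bases (SD, n = 2). Heterochromatic sequences held 28.6% ± 0.0904, U 25.9% ± 3.83 and chromosome 4 4.38% ± 0.0567 (SD, n = 2 for each). Counted as shares of regions in place of bases, heterochromatic sequences held 12.2% and the large arms 58.4%, and in the 50% of each list with the highest scores chromosome 4 held 2.70% of covered bases.

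**Figure D1:**
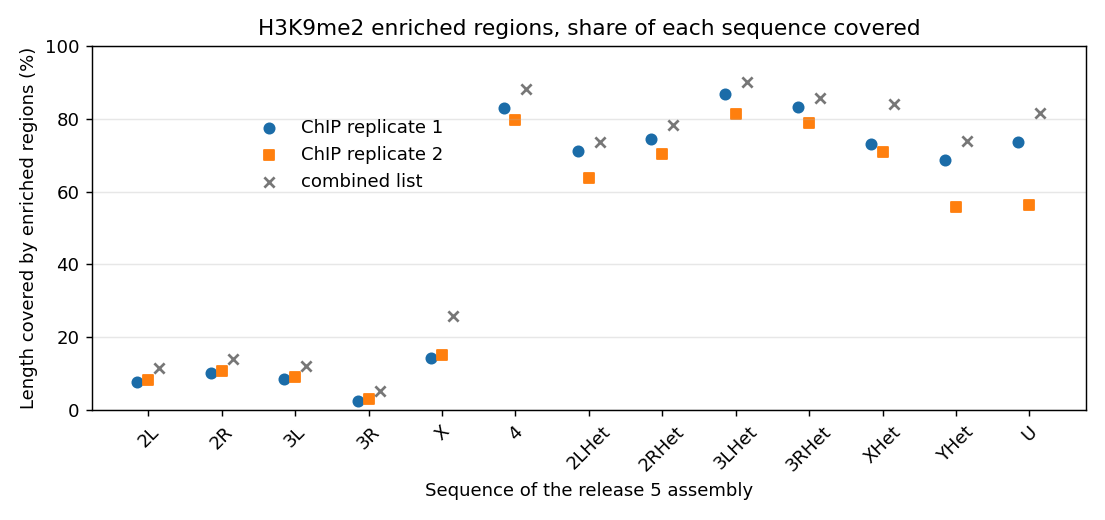
Share of the length of each release 5 sequence (y axis, percent) covered by enriched regions in ChIP replicate 1 (circles), ChIP replicate 2 (squares) and the authors' combined list (crosses). Chromosome 4, the 6 heterochromatic sequences and U have coverage values in the 2 replicates of which the lowest is 55.8% (YHet, replicate 2), whereas the highest large arm, X, reaches 15.2%.

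Among the heterochromatic sequences, coverage was 84.1% ± 3.91 on 3LHet, 81.0% ± 3.10 on 3RHet, 72.4% ± 2.93 on 2RHet, 72.0% ± 1.68 on XHet, 67.4% ± 5.26 on 2LHet and 62.2% ± 9.07 on YHet (SD, n = 2 for each). In both replicates 3LHet was the highest, 3RHet came next, 2LHet lay below 2RHet and XHet, and YHet was the lowest, whereas 2RHet and XHet changed places between replicates. Among the large arms, X was covered over 14.7% ± 0.694, 2R over 10.5% ± 0.444, 3L over 8.85% ± 0.354, 2L over 8.04% ± 0.295 and 3R over 2.67% ± 0.456 (SD, n = 2 for each). The mean over the 6 heterochromatic sequences exceeded that over the 5 large arms by 64.2 percentage points. All heterochromatic sequences lay above all large arms in both replicates (exact permutation test over sequences, two-sided p = 0.00433, the smallest that 462 splits allow). Sequences differ in repeat content and size, so this p describes the sequences and not variation between animals.

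Enriched regions were also longer and scored higher in heterochromatin. The median region length was 7518 bp ± 1945 in heterochromatic sequences, 4980 bp ± 597.2 on chromosome 4, 3670.0 bp ± 1093 on U and 2186 bp ± 146.7 on the large arms (SD, n = 2 for each). The median score was 2.23 ± 0.220 on U, 1.86 ± 0.263 in heterochromatic sequences, 0.845 ± 0.119 on chromosome 4 and 0.704 ± 0.0334 on the large arms (SD, n = 2 for each). Chromosome 4 thus lay near the heterochromatic sequences in the share covered and near the large arms in the score of its regions. In the 50% of each list with the highest scores, the excess of chromosome 4 over the large arms fell from 72.6 to 34.2 percentage points of coverage. That of the heterochromatic sequences over the large arms was 64.9, against 64.2 in the full lists. The chromosome 4 excess was taken over the pooled length of the large arms and the heterochromatic one between means over sequences, so their sizes are not directly comparable.

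The longest region of the combined list lay in heterochromatic sequence. In that class the 3 longest spanned 175.5 kb on 3RHet (520982 to 696494), 163.7 kb on 2RHet (1833174 to 1996828) and 144.0 kb on 3LHet (734776 to 878800). On U the longest spanned 148.7 kb (281606 to 430346), 94.97 kb (5730218 to 5825190) and 81.1 kb (460808 to 541896). On the large arms they spanned 126.0 kb (3L, 23384004 to 23509956), 107.6 kb (2R, 1384086 to 1491646) and 104.1 kb (3L, 23832440 to 23936528). On chromosome 4 they spanned 68.4 kb (1255488 to 1323898), 47.8 kb (901780 to 949540) and 43.6 kb (764814 to 808368). Replicate 1 covered each of these 12 regions by at least 88.6% and replicate 2 by at least 76.7%, with both minima at the longest region of chromosome 4.

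On 3 of the large arms the enrichment formed a dense domain at the centromere-proximal end with much lower coverage in the next window. The proximal domain measured 1.6 Mb on 2R (positions 1 to 1600000), 1.6 Mb on 3L (22943558 to 24543557) and 1.0 Mb on 2L (22011545 to 23011544), with the same length in both replicates at the resolution of 100 kb. Coverage inside was 89.8% ± 1.67 on 2R, 87.1% ± 2.14 on 3L and 81.2% ± 1.63 on 2L (SD, n = 2 for each). In the first window beyond the domain it was 3.34% ± 4.73 on 2R, 19.0% ± 9.10 on 3L and 8.19% ± 4.20 on 2L (SD, n = 2 for each). Over the next 1 Mb it was 21.2% ± 2.11 on 2R, 5.64% ± 1.29 on 3L and 21.6% ± 1.66 on 2L, against 4.02% ± 0.617, 3.40% ± 0.528 and 4.72% ± 0.382 over all sequence outside the domain (SD, n = 2 for each), so that on 2L and 2R coverage rose again beyond the first window. On 2L the length rests on the window: with windows of 50 kb the mean length was 0.425 Mb. Each domain ran to the end of its arm sequence, so these lengths leave out the separately assembled heterochromatic sequences.

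**Figure D2:**
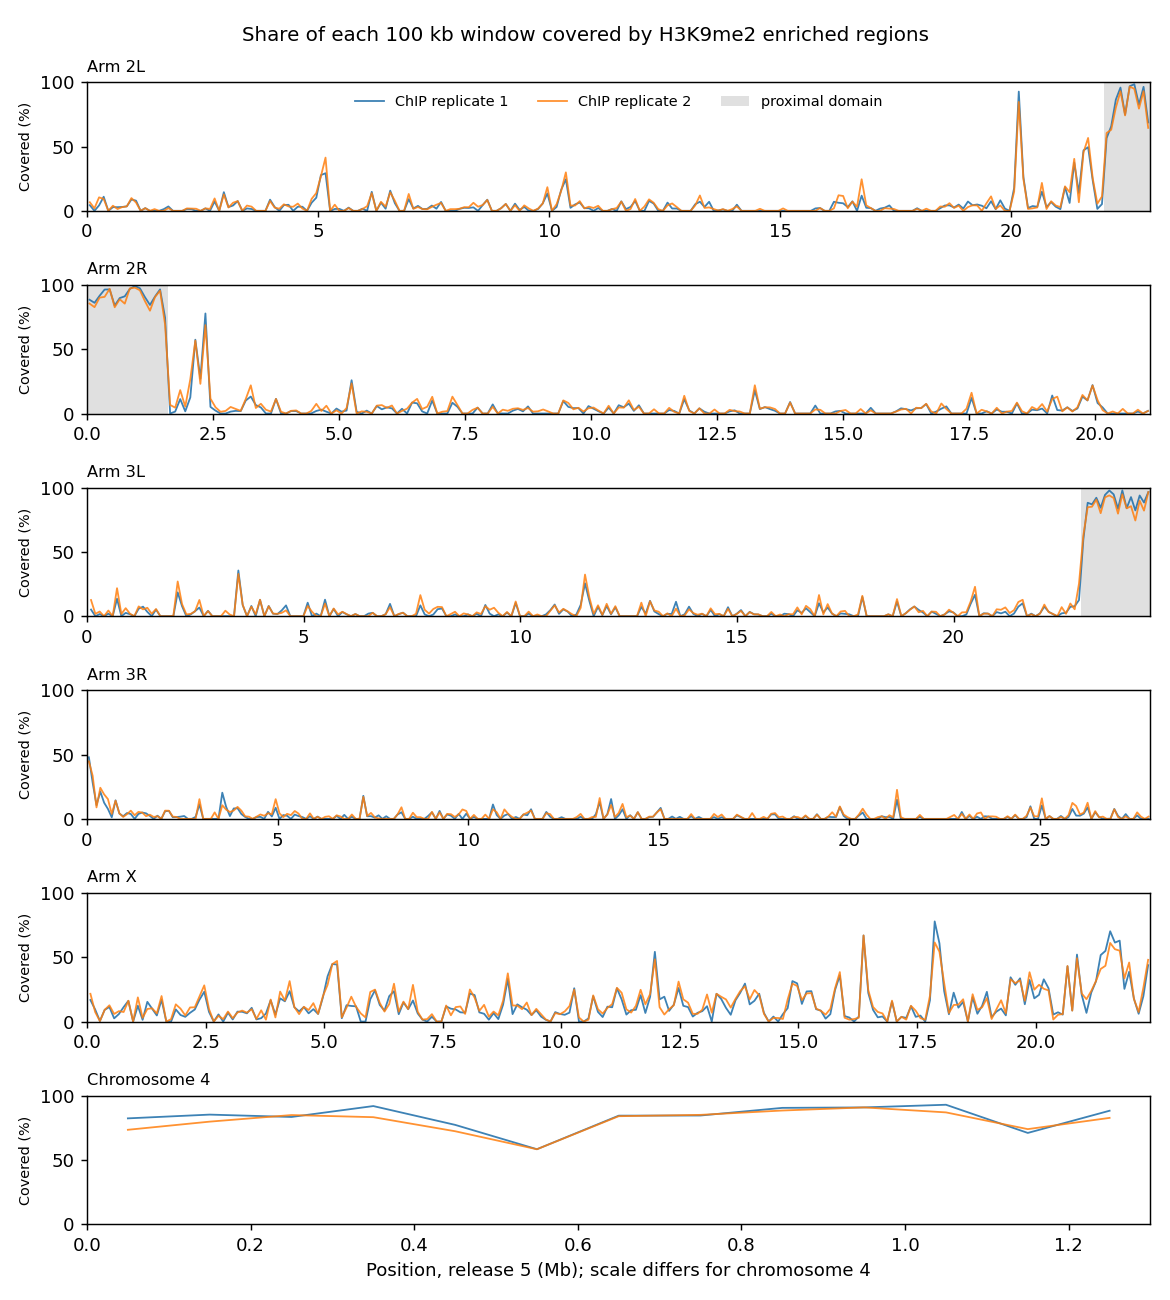
Share of each 100 kb window (y axis, percent) covered by enriched regions along the 5 large arms and chromosome 4 (x axis, position in Mb) in ChIP replicate 1 (blue) and ChIP replicate 2 (orange), with the proximal domain shaded. Dense domains of 1.0 to 1.6 Mb stand at the proximal ends of 2L, 2R and 3L, X shows many partly covered windows along its length, and chromosome 4 is covered over 81.3% of its length.

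On 3R and X no run of windows starting at the proximal end met the threshold of 50% in either replicate. The most proximal window of 3R was covered over 46.3% ± 2.23 and that of X over 46.0% ± 2.92 (SD, n = 2 for each), just under the threshold, and the combined list gave 0.2 Mb on 3R and 0.1 Mb on X. Over the most proximal 2 Mb, coverage was 73.0% ± 0.613 on 2R, 71.5% ± 1.28 on 3L, 51.4% ± 0.0176 on 2L, 32.3% ± 0.290 on X and 9.45% ± 0.903 on 3R (SD, n = 2 for each). The arm sequence of 3R thus carried little of the proximal enrichment seen on the other arms, by a margin well above the spread between replicates. The separately assembled 3RHet was covered over 81.0% ± 3.10 (SD, n = 2), so the low value holds for the arm sequence only.

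Outside the proximal domain, most of the autosomal sequence was free of enriched regions, but several large islands stood out. Most of these islands lay within 3 Mb of a proximal end. Of 100 kb windows outside the domain, 81.4% on 3R, 73.3% on 2R, 72.1% on 3L and 70.5% on 2L were covered by less than 5% in both replicates, against 17.0% on X. Windows covered by at least 50% in both replicates numbered 6 on X, 2 on 2R and 1 on 2L, with 0 of 229 on 3L and 0 of 279 on 3R. The 2L window (20111545 to 20211544) was covered over 88.8% ± 5.69 (SD, n = 2), more than any other window of the large arms outside the proximal domains. On 2R the windows from 2100001 to 2200000 and from 2300001 to 2400000 were covered over 57.1% ± 0.504 and 73.3% ± 6.39 (SD, n = 2 for each). Both lay within 1 Mb beyond the domain. On X, 3 adjoining windows from 21522828 to 21822827 were covered over 65.7% ± 6.44, 58.9% ± 3.66 and 59.1% ± 5.52 (SD, n = 2 for each). They lay in the most proximal 1 Mb of X, which was covered over 39.8% ± 0.457 (SD, n = 2). This stretch counted as outside because X had no domain at the threshold of 50%, so the window counts of X and the autosomal arms are not directly comparable. The other X windows (16322828 to 16422827 and 17822828 to 18022827) were the only ones more than 3 Mb from a proximal end. The longest regions outside the domains fell in or beside these windows: 76.3 kb on X (21758520 to 21834822), 58.0 kb on 2L (20097278 to 20155326), 47.4 kb on 2R (2153194 to 2200622), 43.5 kb on X (17818508 to 17861962) and 40.5 kb on X (21647568 to 21688066). Which genes or repeats these positions hold was not determined here.

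The X chromosome carried more enriched regions outside the proximal domain than any autosomal arm. X had 45.5 ± 6.18 regions per Mb, against 15.4 ± 2.35 on 2L, 13.4 ± 3.80 on 2R, 12.8 ± 3.05 on 3L and 10.9 ± 2.61 on 3R (SD, n = 2 for each). In windows of 1 Mb the density on X was 3.66 times that on the autosomal arms (95% block bootstrap interval 3.02 to 4.45; 22 windows against 90). The permutation test over windows gave a two-sided p of 1e-05, the smallest that 100000 permutations can give, although neighbouring windows are not independent and X is a single chromosome. The ratio was 3.92 in replicate 1 and 3.47 in replicate 2. Since X had no proximal domain to leave out, the ratio was also taken beyond 3 Mb from the proximal end of each arm, where it was 3.59 (3.05 to 4.22). Regions on X differed little in length from those on the autosomal arms: their median was 2292 bp against 2045 to 2219 bp in replicate 1, and 2088 bp against 1897 to 2048 bp in replicate 2. Their median score was 0.759 in replicate 1, against 0.617 to 0.667 on the autosomal arms, and 0.734 in replicate 2, against 0.593 to 0.621.

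**Figure D3:**
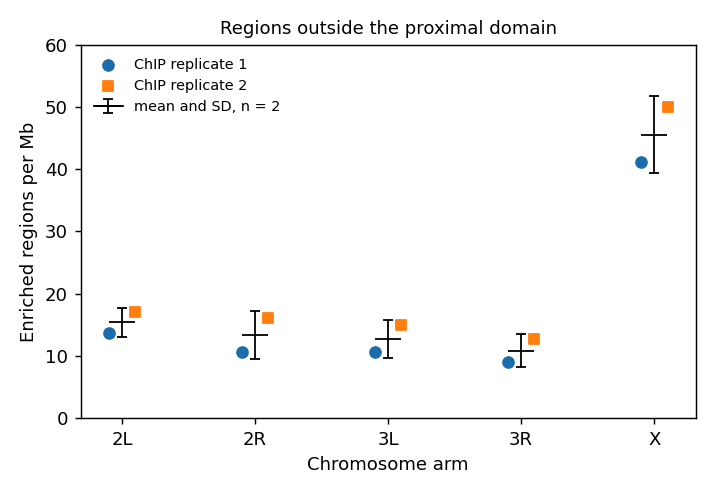
Enriched regions per Mb outside the proximal domain (y axis) on each large arm (x axis) in ChIP replicate 1 (circles) and ChIP replicate 2 (squares), with the mean and SD of the 2 replicates (black). X reaches 41.2 and 49.9 regions per Mb, above all 4 autosomal arms, of which the highest value is 17.0.

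The replicates located the enrichment at largely the same places. They shared 21.7 Mb, which was 83.9% of the bases of replicate 1 and 89.2% of those of replicate 2, and the Jaccard index was 0.762. Circular shifts of replicate 2 gave a mean index of 0.305 and at most 0.398 (one-sided permutation p over shifts = 0.0001, the smallest that 10000 shifts can give). By class, the index was 0.916 in heterochromatic sequences, 0.875 on chromosome 4, 0.730 on U and 0.676 on the large arms, where shifts gave means of 0.636, 0.684, 0.469 and 0.0558. The shared length on the large arms was 7.70 times the shifted mean, with 9.89 times on the 4 autosomal arms and 4.99 times on X. The autosomal value includes the proximal domains, which X lacks, and was not computed without them. On chromosome 4 the shared length was only 1.15 times the shifted mean, since nearly any placement overlaps where most of the sequence is covered. The index was 0.787 on 2R, 0.768 on 3L, 0.714 on 2L, 0.581 on X and 0.493 on 3R.

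Of the regions, 81.7% of those in replicate 1 and 79.7% of those in replicate 2 overlapped the other list by at least 1 bp. When 50% of both regions had to overlap, the shares were 64.2% and 49.8%. Regions in 1 list alone had shorter median lengths and lower median scores. In replicate 1 the 670 such regions had a median length of 1791 bp and a median score of 0.775, against 3818 bp and 1.16 for the 2997 shared ones. In replicate 2 the 960 regions in that list alone had 1602 bp and 0.602, against 3134 bp and 1.25. The medians hide strong single-list regions in replicate 1, where 54.7% of the 179 regions scoring 3 or more were shared, the lowest of the score ranges. In replicate 2 the lowest share was below a score of 1 (63.6% of 2517). The large arms, where scores are low, held 64.0% of the single-list regions of replicate 1 and 96.2% of those of replicate 2. Their share of all regions was 58.1% and 58.7%, so the excess was small in replicate 1 and large in replicate 2. On the large arms alone the median score was 0.642 for the 429 single-list regions against 0.759 for the shared ones in replicate 1, and 0.596 for 924 against 0.756 in replicate 2. Across the 2997 shared regions the scores of the replicates had a Spearman rho of 0.930. Within classes it was 0.828 on the large arms, 0.859 on chromosome 4, 0.785 in heterochromatic sequences and 0.589 on U. These are correlations across regions, which are not independent replicates.

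The combined list held practically all bases common to both replicates, with 0.000184% of them absent, and added many weak regions on the large arms. Of its 5614 regions, 43.5% overlapped both replicate lists, 23.3% overlapped a single one and 33.2% overlapped neither. Of the 1866 regions in neither list, 1733 lay on the large arms, where they made up 39.6% of the combined regions against 6.42% on chromosome 4, 12.8% in heterochromatic sequences and 10.4% on U. These 1733 regions covered 2.44 Mb with a median length of 1273 bp, below the 1301 bp of the shortest region in either replicate list, and a median score of 0.428. The 1488 large-arm regions found in both replicates had medians of 4121 bp and 0.648. The combined list rests on the same libraries and is not an independent measurement.

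The 5 regions with the highest scores in the combined list were short and were each found in only one replicate list. They lay on 3R (6783870 to 6787148, score 4.97), on U (9774074 to 9776228, score 4.84), on U (8108188 to 8111926, score 4.81), on 3RHet (1070452 to 1072468, score 4.70) and on U (2051662 to 2054042, score 4.40). The 3RHet region was covered over 97.3% by replicate 2 and 0% by replicate 1. The others were covered over 39.5% (3R) and 90.4%, 76.7% and 84.0% (U) by replicate 1 and 0% by replicate 2.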

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

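The tested results kept their direction and their side of the threshold under each alternative run: the coverage of heterochromatic sequences against large arms, the agreement of the replicates and the density on X. The values over each replicate list alone ranged from 3667 to 4728 regions and from 24.4 to 25.9 Mb. Leaving out a replicate moved no proximal domain. The minimum of 1000 bp removed no region and tests nothing, whereas a minimum of 2000 bp (chosen after seeing the data) lowered the covered length to 23.0 Mb. The 50% of each list with the highest scores held on average 2098 regions over 19.5 Mb by construction. In that part the shares of covered bases were 28.0% for the large arms, 2.70% for chromosome 4, 36.1% for heterochromatic sequences and 33.2% for U, and the excess of chromosome 4 over the large arms was 34.2 percentage points. Without U the shares were 55.4%, 5.92% and 38.7% for the large arms, chromosome 4 and heterochromatic sequences, a change that the smaller total produces. As shares of regions in place of bases they were 58.4%, 3.32% and 12.2%, because regions on the large arms are short. Reciprocal overlap of at least 50% lowered the shared regions to 64.2% of replicate 1 and 49.8% of replicate 2. Requiring 50% of a combined region gave 36.8% in both replicate lists and 36.0% in neither. Windows of 50 kb gave mean proximal domains of 0.425 Mb on 2L, 1.55 Mb on 3L, 0.05 Mb on 3R and 0.05 Mb on X. A threshold of 25% gave 1.65 Mb on 3L, 0.2 Mb on 3R and 0.15 Mb on X. The cause of these moves was not tested beyond the construction named. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no region lists of their own. The gene list and genomic feature comparisons were not run for lack of a release 5 annotation. Depth is unknown, so a sequence without a region is not shown to lack H3K9me2.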

Other observations

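The uncovered stretches, the ends of sequences, the score ranges and the depleted regions reported here were examined only after the main results had been seen. The tests of explanations were fixed before their own results were seen, but after the patterns themselves. The shift comparison for short gaps and the ratios beyond 3 Mb were added after the results they qualify.

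Heterochromatic sequence was not covered evenly. Stretches of at least 5000 bp with no enriched region in either replicate numbered 28 on 2RHet, 16 on 3RHet, 15 on 3LHet, 12 on YHet, 4 on XHet and 3 on 2LHet. The longest on 2RHet measured 111386 bp (2650062 to 2761447) and 102208 bp (2457160 to 2559367), and the longest on 3RHet 73427 bp (447721 to 521147). The combined list covered 0.119%, 2.18% and 0.474% of these 3 stretches. Of the 78 stretches in heterochromatic sequences it covered 58 by less than 10% and 5 by more than 50%. Chromosome 4 had 7 such stretches, of which the longest measured 13367 bp (425069 to 438435) and 11501 bp (522160 to 533660). These 7 stretches came to 60.5 kb. What these stretches contain was not determined here.

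The distal 100 kb of X was covered over 27.1% ± 3.36 (SD, n = 2), against 8.88% ± 5.27 on 3L, 3.72% ± 1.67 on 2L, 2.01% ± 0.0679 on 2R and 0.886% ± 1.25 on 3R. On chromosome 4 the lowest-coordinate 100 kb was covered over 77.9% ± 6.29 and the highest over 77.5% ± 9.61 (SD, n = 2 for each), so that coverage extended to both ends.

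The excess of enriched regions on X outside the proximal domain is the pattern most open to follow-up. It was not confined to the regions with the lowest scores. In the 25% of regions with the highest scores the X to autosome ratio was 5.49 in replicate 1 (95% block bootstrap interval 4.00 to 7.74). In replicate 2 it was 7.43 (5.14 to 10.9). Beyond 3 Mb from the proximal ends the ratios were 6.11 (4.89 to 7.68) and 7.97 (6.14 to 10.4). The 25% began at a score of 0.905 in replicate 1 and 0.802 in replicate 2, against median X scores of 0.759 and 0.734. A score offset of X would lift weak X calls past these cutoffs, so the ratios cannot exclude that calls near the threshold contribute. Agreement of the replicates argues against chance calls in single libraries for X as a whole, though not for its distal regions by themselves. Replicate 2 overlapped 77.7% of replicate 1 regions on X and 79.1% of those on the autosomal arms. The Jaccard index on X was 0.581, against a mean of 0.0796 and at most 0.484 over circular shifts. The shifts took all of X, including its more densely covered proximal 2 Mb (32.3% ± 0.290, SD, n = 2), and gave no expected value for the 77.7%. Among replicate 1 regions that replicate 2 overlapped the ratio was 3.83 (3.12 to 4.76), or 3.75 (3.11 to 4.48) beyond 3 Mb. That ratio alone cannot decide, because chance calls denser on X in both lists would also overlap more often there. A uniform offset of X, such as a different sex ratio of the larvae behind ChIP and input would give, stays open: the score offset needed was 0.510 at the median and 0.951 at the 90th percentile of autosomal scores in replicate 1, and the difference of 0.441 had an interval of -0.149 to 0.883 (0.264 in replicate 2, interval -0.104 to 0.728, on the assumption that the score is additive). X-linked repeats and a chromosome-wide property of X remain candidate explanations that were not tested here.

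Replicate 2 covered more than replicate 1 on 5 of 5 large arms and on 0 of the 8 other sequences. Replicate 1 alone covered 2.44 Mb in heterochromatic sequences and U. Of this length, 52.9% lay in gaps of at most 5000 bp between replicate 2 regions. The mean over 10000 circular shifts of replicate 1 was 33.6% (one-sided permutation p = 0.0001, the smallest they can give). Replicate 2 lay almost wholly within replicate 1 in these sequences, and shifting breaks that alignment. The p therefore cannot tell domains split by short gaps from plain agreement of the replicates. The 52.9% describes where these bases lay, and whether splitting caused the difference stays open. The score difference of shared regions, replicate 2 minus replicate 1, was more negative in these sequences than on the large arms (medians -0.293 and -0.0492). The gap was -0.244 score units (95% bootstrap interval -0.265 to -0.224, over regions and not between libraries). Lower enrichment of these sequences in replicate 2 may contribute, and library depth, which is unknown, could act the same way. The design names no biological difference between the replicates, so no biological explanation was tested.

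The combined list held 1.58 times as many regions on the large arms as the larger replicate list. Restricted to its 3346 large-arm regions of at least 1301 bp, the ratio was 1.21, so that the shorter minimum length may account for much of the excess but cannot be told apart from a lower threshold, since regions just above the minimum could have been shorter in a single library. Large-arm regions in neither replicate list had a median score of 0.428, against a 10th percentile of 0.437 among those in both, but a low score follows from choosing regions that single libraries missed, so whether the threshold differed stays open. In heterochromatic sequences the medians went the other way, 2.23 for regions in neither list and 1.86 for those in both.

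The share of regions found in both lists varied with the score. In replicate 1, 54.7% of 179 regions with a score of 3 or more overlapped the other list, against 86.8% of 973 with a score from 2 to 3, 91.4% of 793 from 1 to 2 and 77.2% of 1722 below 1. In replicate 2 the shares in the same order were 88.6% of 149, 98.2% of 675, 98.9% of 1387 and 63.6% of 2517, lowest below a score of 1. U held 77.1% of these high-scoring regions in replicate 1 and 83.9% in replicate 2. These high-scoring regions had median lengths of 2689 bp and 2007 bp.

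A region on 2R was listed as depleted both in replicate 2 (5987203 to 5988850, score -0.00452) and in the combined list (5987192 to 5988828, score -0.0643), and no list held an enriched region there. A second depleted region of the combined list lay on 3R (22701104 to 22702754, score -0.00616) and overlapped an enriched region in 1 of the 3 lists.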
